A study of Mus musculus with 5 samples.

How the data were processed

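The data were UMI counts from single mouse cells in 5 libraries, 1 for each of Days 0, 1, 3, 7 and 10. Per the labels, the cells were progenitors from white subcutaneous fat, and all libraries after Day 0 came from cells in cardiac transition. Libraries were made with the 10x Genomics Chromium 3′ kit, version 3, per the labels' protocols. In this assay each droplet gives its cell a barcode and each captured polyadenylated RNA a unique molecular identifier (UMI), so that copies made by PCR are counted once. The authors deposited raw UMI counts for 31053 Ensembl gene IDs and every barcode they had retained, with no normalization. Reads were processed with Cell Ranger against the mouse genome build mm10, per the submitters' processing notes. The Cell Ranger version, the annotation release and whether intronic reads were counted were not given in the sources used here. The lowest barcode total was 1540 UMIs on Day 0 and between 500 and 510 UMIs on the other days, so barcodes of low count had been left out before deposit by a rule not given in the sources used here. Counting at the 3′ end does not separate transcript isoforms.

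Gene symbols and coordinates were taken by gene ID from GENCODE M21, which annotates the same assembly, and 30934 of the 31053 IDs matched. The 119 IDs without a symbol held 0.019% of UMIs. Where a symbol belonged to several IDs, the ID with the most UMIs carried it. Cells were kept when they had at least 500 detected genes, at least 1000 UMIs and under 20% mitochondrial UMIs. Scrublet was run per library and marked 65 barcodes on Day 1, 44 on Day 3, 221 on Day 7 and 364 on Day 10, which were removed. It marked 0 on Day 0 and was taken as not having worked there. The filters kept 4089 of 11093 barcodes on Day 0, 5208 of 6499 on Day 1, 4645 of 5224 on Day 3, 7198 of 7740 on Day 7 and 8844 of 9725 on Day 10. On Day 0, 7004 barcodes were left out for their mitochondrial share.

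UMIs were summed per gene over the kept cells of a library and given as CPM, the gene's UMIs scaled to a fixed total for every library. With 1 library per day there was no replicate, so no test was run and no p-value computed. Values carry exact Poisson intervals for sums and exact Clopper-Pearson binomial intervals for shares of cells, all at 95% and all covering counting error only. A count of 0 was given the limit of 3 counts. At 20 CPM the Day 0 sum held 265.5 UMIs, with an interval of 17.7 to 22.6 CPM, and the Day 10 sum held 2923 UMIs, with an interval of 19.3 to 20.7 CPM. Each later day was set against Day 0, and each day against the one sampled before it. A gene was counted as higher or lower when the ratio of CPM + 1 was at least 2-fold and the higher library had at least 20 CPM. Ratios on this scale understate differences of genes near 1 CPM.

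The 51 gene lists, made of cell type markers and of pathways, the filters, the comparisons and most alternatives were fixed before the data were examined. For each list the median log2 ratio was taken over members with at least 2 CPM on average, with its percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Members were counted as higher or lower at a 2-fold ratio of CPM + 1, without the floor of 20 CPM. Lists with under 3 such members got no median. Genes were named by a rule fixed at the same time. It took the 10 genes with the largest ratio each way against Day 0 and the 5 each way against the day before, among genes with at least 20 CPM in the higher library and without mitochondrially encoded, ribosomal protein and hemoglobin genes. It added up to 4 members with the largest absolute log2 ratio from each list described, and any member of the cardiomyocyte markers and cardiac transcription factors. Genes outside the rule are said to have been chosen after their values were seen. Values of some single genes that the rule allows are not reported here.

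Kept cells of all libraries were clustered together without batch integration, since day and library were the same thing. The steps used 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5, and gave 22 clusters. A cluster was called X-like when at least 2 of its 10 leading genes were markers of class X. At least 3 markers of X also had to be found in 20% or more of its cells. Among the leading genes, markers of X had to outnumber those of all other classes together. A tie sufficed if the first leading gene was a marker of X. The minimum of 2 leading markers was set after the clusters were seen. Shares of cells with a UMI and cycling shares were computed after each cell was thinned to 1000 UMIs, the largest tried depth that kept at least 80% of the kept cells of every library, and no kept cell was shallower. A cell was counted as having S or G2/M phase transcripts with at least 2 UMIs from the list.

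The counting step was tested on simulated data, drawn for both libraries from a single profile with counting noise alone. For every comparison it recovered 100.0% of 200 genes changed 4-fold and called 0 unchanged genes. This was on between 5054 genes, for Day 7 against Day 0, and 5517 genes, for Day 7 against Day 3. Without variation between libraries beyond counting, the simulation gives no rate of false calls for the real comparisons. Of 200 simulated lists of 14 unshifted genes for Day 7 against Day 0, 6.5% lay outside the central 95% of matched random lists, over 11606 genes. Alternatives changed 1 choice at a time, namely the cell filter, doublet removal, scaling by TMM or by median-of-ratios factors, the floor, the pseudocount, cell weighting, thinning, cluster resolution and thresholds per cell. Alternatives added after seeing the data left out the Day 0 library, mitochondrially encoded genes, genes on X and Y, the cells with the highest 5% of Scrublet scores, or the erythroid-like, B-like and mast-like cells. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, anndata 0.12.19 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for scaling factors alone.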

Results

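The series followed cells of mouse white subcutaneous fat through a culture in which leukemia inhibitory factor (LIF), a cytokine that signals through its receptor and STAT3, was named as the inducer of a cardiac transition. 1 library of single cells was sequenced on each of Days 0, 1, 3, 7 and 10. After filtering, the libraries held 4089, 5208, 4645, 7198 and 8844 cells and 13272760, 108320249, 95355211, 123925562 and 146127925 UMIs. The median cell had 2443 UMIs on Day 0, against 22024.5, 18901, 14000 and 14209.5 UMIs on the later days. The median share of mitochondrial UMIs was 15.1% on Day 0 and 2.24%, 4.39%, 5.75% and 4.92% later. No culture without LIF was analysed here, and each difference between days is also a difference between 2 libraries with no replicate.

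The Day 1 library differed from the others in sex-linked transcripts. Xist, the noncoding RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254, mm10), was at 933, 0.037, 469, 404 and 580.0 CPM on Days 0, 1, 3, 7 and 10. The Y-linked genes Ddx3y (chromosome Y, 1260771 to 1286629), Eif2s3y (1010543 to 1028847), Kdm5d (897788 to 956786) and Uty (1096861 to 1245759) together were at 99.3 CPM (97.4 to 101) on Day 1 and at 0.075 and 0.010 CPM on Days 0 and 3. They had no UMI on Days 7 and 10, which allows up to 0.0242 and 0.0205 CPM. Kdm5d and Uty were chosen after their values were seen. This difference goes with every comparison that involves Day 1.

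**Figure D1:**
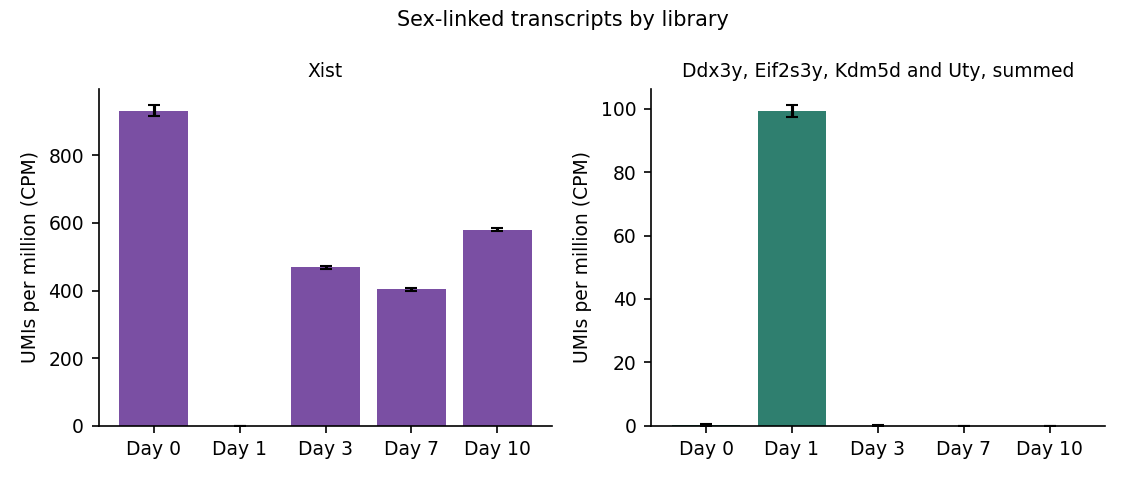
CPM of Xist and of 4 Y-linked genes summed (vertical axes) in each library (horizontal axis), with exact Poisson 95% intervals as error bars. Xist is at 0.037 CPM on Day 1 and between 404 and 933 CPM on the other days, while the Y-linked genes are at 99.3 CPM on Day 1 and at most 0.075 CPM on the other days.

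Cells with fat cell, endothelial, macrophage and muscle markers took different shares of the libraries. The preadipocyte or adipocyte-like class held 91.1% of Day 0 cells (90.2 to 91.9) and at most 0.038% of any later library. The endothelial-like class, the cells that line vessels, held 23.2% of Day 1 (22.0 to 24.3) and 15.8% of Day 3 (14.8 to 16.9), mainly in cluster 8, then 0.278% of Day 7 and 1.14% of Day 10, where cluster 16 held most. No Day 0 cluster was endothelial-like, but cluster 1, which held 7.39% of Day 0 and stayed unnamed, had Gpihbp1 and Cldn5 among its leading genes beside hemoglobin genes. Endothelial markers were higher in 3 and lower in 2 of 12 on Day 1 against Day 0 (median 0.17). Macrophage or monocyte-like cells made up 0.293%, 5.13%, 1.77%, 0.278% and 0.237% over the 5 days, and Schwann-like cells, the glia of peripheral nerves, 0.318%, 1.67%, 2.71%, 1.76% and 1.73%. The Schwann-like cells of Day 0 were all in cluster 6 and the later ones in cluster 12. Their Day 0 share was 0% with doublets kept and 0.126% without a cell filter, and all 4 measured Schwann markers were lower on Day 1 than on Day 0 (median log2 ratio −2.86). Erythroid-like cells held 0.611% of Day 0 and 1.31% of Day 1, but 0.216% and 3.25% without a cell filter. B-like cells held 0.318% and 1.48%, with 0% on Day 0 without a cell filter or with each library clustered on its own, and mast-like cells 0.595% of Day 1. The skeletal muscle-like class of clusters 18 and 19 held 0.388% of Day 3, 23.4% of Day 7 (22.4 to 24.4) and 19.6% of Day 10 (18.8 to 20.4). Unnamed clusters 11 (0.979% of Day 1) and 15 had the skeletal muscle marker Myod1 among their leading genes. Unnamed cluster 21 had no marker there. At a resolution of 1.0, 326 of its Day 10 cells fell in a cluster with Pax7, a muscle stem cell gene, among its leading genes. Clusters 11, 15, 18, 19 and 21 together held 0.999% of Day 1, 6.18% of Day 3, 57.1% of Day 7 and 40.9% of Day 10. The adipose progenitor or fibroblast-like class held 1.32% of Day 7 and 45.9% of Day 10 (44.8 to 46.9), all in cluster 17, which may therefore be that library and not a type. No cluster was cardiomyocyte-like at this resolution.

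The names of several classes depended on the clustering. At a Leiden resolution of 1.0, 1.33% of Day 7 and 13.96% of Day 10 cells were cardiomyocyte-like. Their cluster was led by Ttn, Actc1 and Tnnt2, which skeletal muscle or its embryonic form also makes, together with the skeletal muscle markers Myh1 and Ckm. Of its 1331 cells, 1330 belonged to skeletal muscle-like cluster 19 at a resolution of 0.5 and 1 to cluster 18. Skeletal muscle-like cells then held 5.63% of Day 10, fibroblast-like cells 14.1% of Day 10 and endothelial-like cells 1.85% of Day 3 and 0.014% of Day 7. Adipocyte-like cells held 2.41% of Day 3. T or NK-like cells held 1.57% of Day 1, and these 82 cells were among the 267 of macrophage-like cluster 5. With each library clustered on its own, no Day 0 cluster was adipocyte-like and no Day 10 cluster fibroblast-like. Leading genes were then ranked against the other cells of the same library, which works against a class that fills it. Day 0 clusters of 1667, 850, 816 and 346 cells stayed unnamed, though each of the 12 adipocyte markers was found in 20% or more of their cells. In this clustering 1.76% of Day 0 was progenitor or fibroblast-like, 6.43% of Day 0 endothelial-like and 10.3% of Day 3 pericyte or smooth muscle-like. On Day 3, 6.20% of cells were then skeletal muscle-like and 3.32% adipocyte-like. On Day 1, 3.40% were macrophage-like and 1.57% T or NK-like, and macrophage-like cells held 0% of Day 0 and 0.667% of Day 7. Unnamed clusters held 7.39%, 66.6%, 79.2%, 73.0% and 31.4% of cells. Most of them belonged to 1 library, with cluster 7 at 61.5% of Day 1, cluster 10 at 52.3% of Day 3, clusters 15 and 20 at 32.9% and 32.6% of Day 7 and cluster 21 at 20.1% of Day 10. Had 1 leading marker sufficed, cluster 7 would have been fibroblast-like, cluster 9 (1.82%, 9.77%, 1.39% and 0.407% of Days 1, 3, 7 and 10) pericyte or smooth muscle-like and cluster 15 (5.71%, 32.9% and 1.14% of Days 3, 7 and 10) skeletal muscle-like. Cluster 20, with 32.6% of Day 7 and 6.28% of Day 10, would have stayed unnamed. It had 1 leading marker of pericytes or smooth muscle and 1 of another class.

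**Figure D2:**
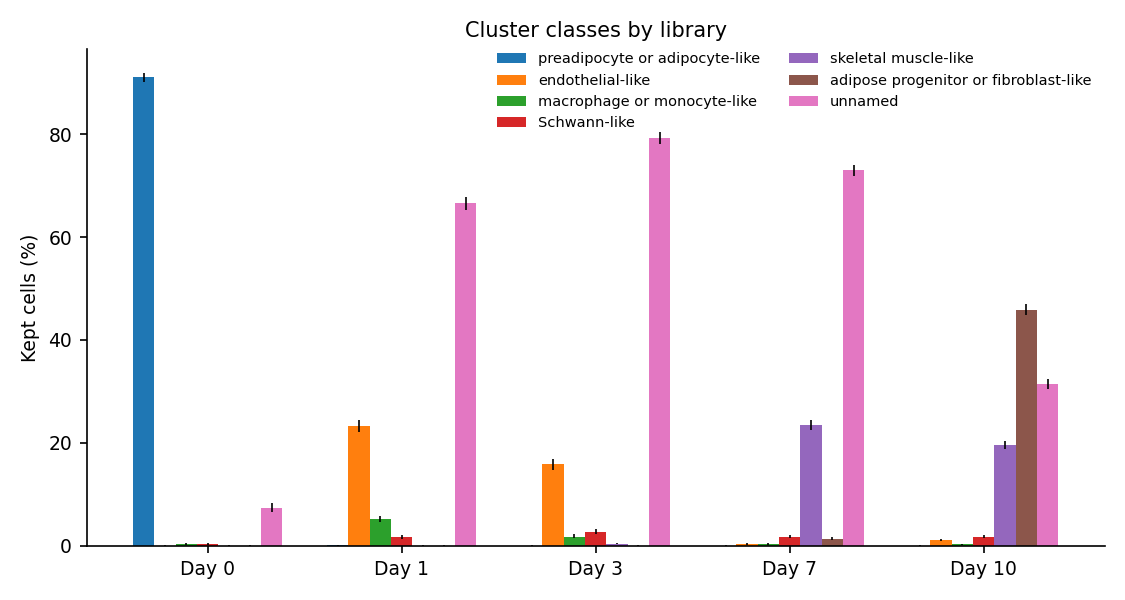
Share of kept cells in percent (vertical axis) in each named class and in unnamed clusters, by library (horizontal axis), with exact binomial 95% intervals as error bars. Adipocyte-like cells hold 91.1% of Day 0, endothelial-like cells 23.2% of Day 1 and skeletal muscle-like cells 23.4% of Day 7.

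On Day 1, 1 day into the culture, genes of fat cells were lower than on Day 0. All 12 measured preadipocyte or adipocyte markers were at least 2-fold lower, with a median log2 ratio of −7.50 (percentile 0.00 of matched random lists). Adipoq, the hormone adiponectin (chromosome 16, 23146536 to 23158028), was at 3184 CPM (3154 to 3215) on Day 0 and 5.57 CPM on Day 1 (log2 ratio −8.92). Car3, a carbonic anhydrase abundant in fat, was at 17819 and 56.0 CPM and Retn, the hormone resistin, at 4424 and 14.9 CPM. The lipid droplet coat genes Plin1 and Plin4 were at 724 and 1.99 CPM and 1233 and 3.07 CPM. The esterase gene Ces1d (1039 and 1.60 CPM), Pck1, an enzyme of glyceroneogenesis (1053 and 2.84 CPM), the adrenergic receptor gene Adrb3 (345 and 0.305 CPM) and the desaturase gene Scd1 (7224 and 30.2 CPM) were also among the 10 largest ratios downward. Of 12 adipogenic regulators 9 were lower and 0 higher (median −3.77), led by Lpin1 at 199 and 1.65 CPM and Cebpa, a transcription factor of fat cell differentiation, at 388 and 6.99 CPM. Of 13 genes of fatty acid synthesis and oxidation 12 were lower (median −2.42), with Fasn at 905 and 41.8 CPM.

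Most contractile, chemokine and oxidative defence genes of the fixed lists were higher on Day 1. Timp1, an inhibitor of matrix proteases (chromosome X, 20870166 to 20874735), was at 0.527 CPM (0.212 to 1.09) on Day 0 and 1413 CPM (1406 to 1419.9) on Day 1. Il1rl1, the interleukin-33 receptor, was at 0.226 and 657 CPM, Inhba, the activin A subunit, at 0.226 and 446 CPM and Pdpn, podoplanin, at 1.58 and 533 CPM. Hmga2, a chromatin protein of embryonic and proliferating cells, was at 0.226 and 144 CPM and the calcium-binding protein gene S100a4 at 3.39 and 499 CPM. Serpinb2 had no UMI on Day 0, which allows 0.226 CPM, and 156 CPM on Day 1, and 3300005D01Rik was at 0.075 and 185 CPM. Of 15 smooth muscle contractile and myofibroblast genes 12 were at least 2-fold higher and 0 lower (median 3.18, percentile 100). Among them were Ccn2, a matricellular growth factor, at 0.979 and 536 CPM and the actin-binding genes Tpm2 and Tagln at 3.01 and 234 CPM and 18.6 and 880.1 CPM. Of 11 pericyte or smooth muscle markers, in contrast, 0 were higher and 7 lower (median −1.08). Of 19 chemokines and cytokines 11 were higher and 5 lower (median 2.79, percentile 100). Cxcl5 was at 0.301 and 332 CPM, Csf1 at 49.3 and 1282 CPM and, in the other direction, the interferon-induced Cxcl10 at 761 and 17.3 CPM. Of 12 NRF2 and metallothionein genes 8 were higher and 3 lower (median 2.79). The heme oxygenase gene Hmox1 was at 27.9 and 1303 CPM and the cystine transporter gene Slc7a11 at 3.92 and 149 CPM. Immediate early and dissociation stress genes were lower in 14 of 16 and higher in 1 (median −3.40), with Fos at 1571 and 27.8 CPM and Egr1 at 2126 and 57.5 CPM.

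In all, 1995 genes were higher and 1543 lower on Day 1 than on Day 0. Markers of macrophages (6 of 11 higher, median 2.04; Fcer1g at 4.52 and 50.7 CPM), neutrophils (3 of 3 higher, 2.05; S100a8 at 1.81 and 14.4 CPM) and mast cells (2 of 3 higher, 3.75; Tpsb2 with no UMI and 15.9 CPM) were also higher. The cutoff of 2 CPM on average includes Day 1 and left out most neutrophil and mast markers, so it partly sets these counts. Hemoglobin genes of the erythroid list were lower (4 of 4, median −4.40; Hbb-bs at 3226 and 151 CPM), although without a cell filter that median was 0.41. With only cells under 10% mitochondrial UMIs, of which Day 0 had 444 before doublet removal, the split was 1606 higher and 1756 lower, and the median of the progenitor or fibroblast markers was −0.59 in place of 1.496.

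Day 3 was set against Day 0 to see what differed 3 days into the culture, and Timp1 had the largest ratio upward. Contractile and cell division genes were also among the 10 largest. Tagln was at 18.6 and 2828 CPM on Days 0 and 3, Tpm2 at 3.01 and 1327 CPM, Ankrd1, a stretch-responsive cofactor of muscle, at 0.075 and 375 CPM, and Ptgs2, the inducible cyclooxygenase, at 1.13 and 757 CPM. Timp1 was at 2024 CPM, Inhba at 1371 CPM, Ccn2 at 605 CPM, Hmga2 at 298 CPM and S100a4 at 716 CPM on Day 3. All 20 measured G2/M phase genes were higher, with a median log2 ratio of 5.23 (percentile 100), among them Birc5, survivin, at 0.377 and 189 CPM and Top2a, a topoisomerase of dividing cells, at 0.829 and 149.6 CPM. Of the smooth muscle contractile and myofibroblast genes 14 of 15 were higher (median 5.001), with Acta2, smooth muscle actin, at 48.1 and 3129 CPM, while pericyte or smooth muscle markers were higher in 3 and lower in 4 of 11 (median 0.24). In the TGF-beta and BMP list 9 of 15 were higher and 2 lower (median 2.26, percentile 99.95). Tgfb2 was at 1.13 and 59.5 CPM, Fst, an activin antagonist, at 5.58 and 168 CPM and Grem1, a BMP antagonist, with no UMI and 19.9 CPM. Epicardial and epithelial-to-mesenchymal transition genes were higher in 8 of 12 and lower in 2 (median 2.13, percentile 99.95). N-cadherin, Cdh2, was at 2.34 and 74.9 CPM, Snai1 at 2.34 and 54.4 CPM, Fn1, fibronectin, at 28.9 and 364 CPM and Tbx18 at 1.36 and 26.9 CPM.

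Cfd, the adipokine adipsin (chromosome 10, 79890853 to 79892655), had the largest ratio downward, at 35056 and 6.47 CPM on Days 0 and 3 (log2 ratio −12.20). Retn, Car3 and Adipoq were at 1.10, 8.19 and 1.11 CPM on Day 3, Ces1d and Pck1 at 0.136 and 0.252 CPM, and Apoe, an apolipoprotein, at 5298 and 9.62 CPM. Thrsp, a regulator of fat synthesis, was at 1035 and 0.451 CPM, and Cidec and Adig, proteins of the fat cell, at 1455 and 1.06 CPM and 964 and 0.682 CPM. All 12 adipocyte markers (median −7.18) and all 10 complement genes (median −4.07) were lower, with C4b at 409 and 1.18 CPM and C3 at 488 and 1.75 CPM. In all, 2373 genes were higher and 1427 lower on Day 3 than on Day 0.

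On Day 7 Timp1 had the largest ratio upward against Day 0 (log2 ratio 10.58), followed by Mylpf, Tnnc1, Ttn and Tnnt1, genes of striated muscle. Mylpf, the fast skeletal regulatory light chain (chromosome 7, 127208890 to 127214298), was at 2.49 CPM (1.71 to 3.49) on Day 0 and 3406 CPM (3396 to 3417) on Day 7 (log2 ratio 9.93). Tnnc1, the troponin C of heart and slow skeletal muscle, was at 0.452 and 1124 CPM, the giant sarcomere protein gene Ttn (chromosome 2, 76703980 to 76982547) at 0.151 and 841 CPM, and the skeletal troponin T genes Tnnt1 and Tnnt3 at 0.527 and 1021 CPM and 0.452 and 715 CPM. All 9 measured skeletal muscle markers were higher (median 7.14, percentile 100). Among them were the myogenic transcription factors Myog (chromosome 1, 134289989 to 134292548), with no UMI on Day 0 and 464 CPM on Day 7, and Myod1 (chromosome 7, 46376474 to 46379099), with no UMI and 321 CPM. No UMI on Day 0 allows 0.226 CPM. All 6 measured cardiomyocyte markers were higher too (median 8.50, percentile 100), among them genes that skeletal muscle also makes. The other cardiomyocyte markers had under 2 CPM on average and were left out. That average includes Day 7, so the counts of measured skeletal muscle and cardiomyocyte markers are partly set by this cutoff. Of 8 genes of cardiac ion handling and junctions 7 were higher (median 1.98), with the calcium store genes Casq2 at 0.075 and 49.4 CPM, Jph2 at 0.151 and 29.0 CPM and Trdn at 0.226 and 18.2 CPM. The imprinted RNA H19 was at 0.603 and 941 CPM, Tpm2 at 2396 CPM, S100a4 at 2182 CPM and Timp1 at 2340.2 CPM. Sct, the hormone secretin (chromosome 7, 141278330 to 141279133), had no UMI on Day 0 and 514 CPM on Day 7.

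Genes of MHC class I presentation, interferon response and complement were mostly lower on Day 7 than on Day 0. All 12 genes of MHC class I presentation were lower (median −4.01). H2-K1 was at 1186 and 27.3 CPM and Psmb9, a subunit of the immunoproteasome, at 57.2 and 0.387 CPM. In addition, 13 of 15 interferon response genes were lower and 1 higher (median −2.75), with Ifi27l2a at 7706 and 4.73 CPM and Irf1 at 352 and 3.76 CPM. All 10 complement genes (median −4.88), all 12 adipocyte markers (median −8.67) and 11 of 12 endothelial markers (median −3.42; Cldn5 at 210.1 and 0.065 CPM) were lower. Chemokines and cytokines were lower in 10 and higher in 5 of 19 (median −1.35). Macrophage markers were lower in 2 and higher in 2 of 11 (median 0.05). Cfd was at 0.234 CPM, Retn at 0.307 CPM, Adipoq at 0.218 CPM, Apoe at 3.04 CPM, Cidec at 0.21 CPM, Thrsp at 0.016 CPM, Pck1 at 0.137 CPM and Adig at 0.089 CPM on Day 7, and Ces1d had no UMI. In all, 2190 genes were higher and 1443 lower on Day 7 than on Day 0.

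On Day 10, the last day sampled, Ttn had the largest ratio upward against Day 0, at 1692 CPM (1686 to 1699; log2 ratio 10.52). Tnnt2, the troponin T of heart and embryonic skeletal muscle (chromosome 1, 135836354 to 135852260), was at 1.13 and 894 CPM on Days 0 and 10. Actc1, cardiac alpha actin, which embryonic skeletal muscle also makes (chromosome 2, 114047282 to 114053548), had no UMI and 607 CPM. Myh3, the embryonic skeletal myosin heavy chain (chromosome 11, 67078300 to 67102291), had no UMI and 604 CPM. Mylpf was at 2376 CPM, Tnnc1 at 970.5 CPM, Tpm2 at 2528 CPM, Tnnt1 at 554 CPM, H19 at 773 CPM and Timp1 at 1558 CPM on Day 10. All 9 skeletal muscle markers (median 6.96) and all 6 measured cardiomyocyte markers (median 8.98) were higher. As on Day 7, the cutoff of 2 CPM on average partly sets both counts. Of 16 fibrillar collagen and matrix genes 13 were higher and 2 lower (median 3.29, percentile 100). Fn1 was at 28.9 and 1083 CPM, Fbn1, fibrillin, at 14.01 and 478 CPM and Col1a1 at 96.7 and 2333 CPM, while Lum was at 24.2 and 0.103 CPM. Of the 12 progenitor or fibroblast markers 9 were higher and 3 lower (median 3.06), with Thy1 at 4.45 and 278 CPM and Dcn at 171 and 6.97 CPM. As 91.1% of Day 0 cells were adipocyte-like, these ratios do not separate a different mix of cells from a change within cells. With Day 0 clustered on its own, such markers named 72 cells progenitor-like. In these cells Col3a1 was at 6276 CPM, Col1a2 at 3229 CPM and Dcn at 6215 CPM, values looked at after the results were seen.

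Downward, Cfd again had the largest ratio, at 0.157 CPM on Day 10 (−14.89), and Car3, Retn, Ifi27l2a and Adipoq were at 3.81, 0.301, 1.55 and 0.267 CPM. Cidec, Thrsp, Pck1 and Adig were at 0.007, 0.034, 0.062 and 0.014 CPM, and Ces1d had no UMI, which allows 0.0205 CPM. In all, 2391 genes were higher and 1272 lower on Day 10 than on Day 0. Median-of-ratios factors gave 1834 higher and 1518 lower. Against Day 0 the median log2 ratio of all genes was 0.16, 0.34, 0.31 and 0.47 on Days 1, 3, 7 and 10 in CPM. It was 0.27, 0.26, 0.31 and 0.36 with TMM factors and 0.20, 0.18, 0.22 and 0.23 with median-of-ratios factors, and the list medians are to be read relative to it.

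**Figure D3:**
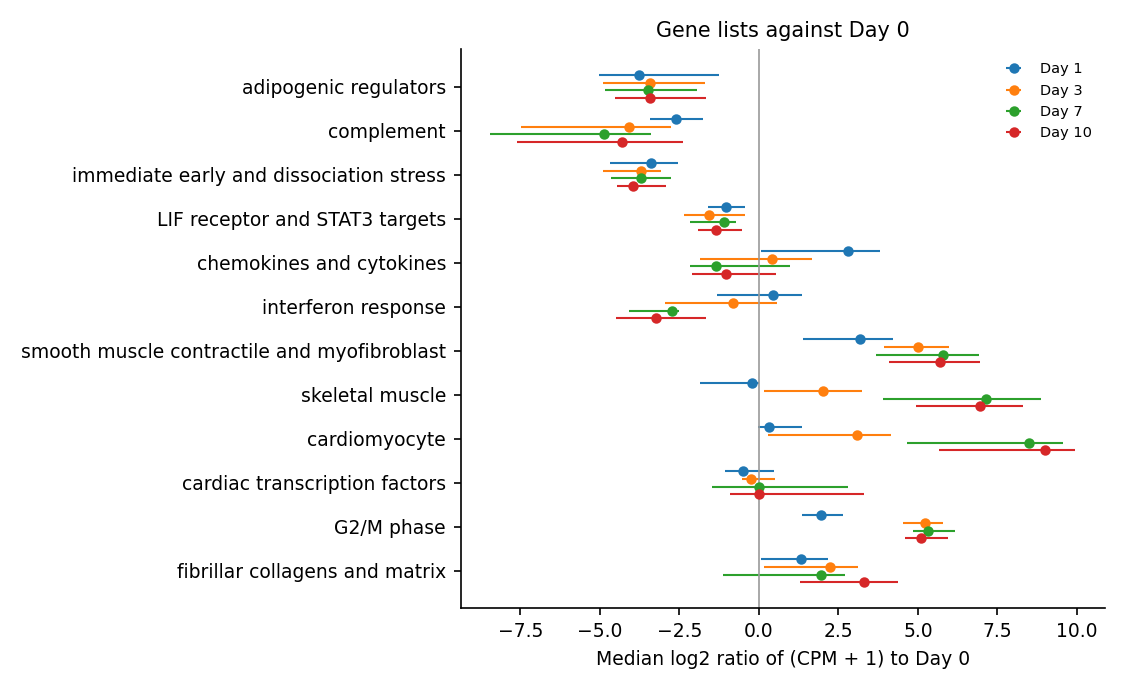
Median log2 ratio of CPM + 1 against Day 0 (horizontal axis) of 12 gene lists (vertical axis) on Days 1, 3, 7 and 10 (colours), with bars for the 95% bootstrap interval over list members. Members with under 2 CPM on average over the libraries are left out. The skeletal muscle list is at −0.23 on Day 1 and 7.14 on Day 7, and the adipogenic regulators lie between −3.77 and −3.41 on the 4 days.

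Between Days 1 and 3, G2/M phase genes and most smooth muscle contractile genes were higher on the later day, and most chemokines lower. All 20 G2/M phase genes were higher (median 3.14), with Cenpa, a centromere histone, at 4.93 and 104 CPM and Hmmr at 4.20 and 82.9 CPM. Of 11 pericyte or smooth muscle markers 7 were higher and 0 lower (median 1.32). Cnn1, calponin, was at 0.499 and 63.3 CPM and Myh11, the smooth muscle myosin, at 2.58 and 37.4 CPM. Further, 9 of 15 smooth muscle contractile and myofibroblast genes were higher (median 1.88), with Actg2 at 0.637 and 29.8 CPM. Of the 19 chemokines and cytokines 12 were lower and 0 higher (median −1.85), with Ccl5 at 76.6 and 2.32 CPM and Ccl8 at 71.3 and 4.69 CPM. Markers of immune cells moved with them. Macrophage markers were lower in 5 and higher in 1 of 11 (median −0.38), dendritic markers lower in all 4 (median −2.40), and neutrophil and mast markers in 2 of 3 each (medians −1.98 and −3.72). For the short lists the cutoff of 2 CPM on average, which includes Day 1, partly sets these counts. Macrophage-like cells went from 5.13% to 1.77%, and in the Day 1 cells of their cluster 5, which include the 82 T or NK-like cells, Ccl5 was at 2856 CPM. Further, 8 of 10 complement genes were lower, with C3 at 89.1 and 1.75 CPM and Cfd at 185 and 6.47 CPM. Sct was at 0.138 and 76.7 CPM and H19 at 0.138 and 39.4 CPM. The other genes at the ends of the ranking were sex-linked, with Xist and its antisense RNA Tsix, which had no UMI on Day 1, at 469 and 36.3 CPM on Day 3, and Ddx3y and Eif2s3y at 50.3 and 36.9 CPM on Day 1 and without a UMI on Day 3. Overlapping antisense reads of Xist and Tsix can be told apart only if strand was used in counting, which was not given in the sources used here. In all, 499 genes were higher and 149 lower. TMM factors gave 358 higher and 263 lower, and median-of-ratios factors 353 and 266.

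Between Days 3 and 7, measured skeletal muscle and cardiomyocyte markers were higher on Day 7 and endothelial markers lower. All 9 skeletal muscle markers (median 5.71) and all 6 measured cardiomyocyte markers (median 5.54) were higher, both at percentile 100. Here too the cutoff of 2 CPM on average partly sets both counts. The light chain genes Myl1 and Myl4 were at 5.11 and 944 CPM and 8.47 and 862 CPM, Mylpf at 25.6 and 3406 CPM, the fast troponin C gene Tnnc2 at 5.57 and 765 CPM and Myh3 at 3.44 and 444 CPM. All 12 endothelial markers were lower (median −3.08), with the junction genes Cldn5 and Cdh5 at 31.8 and 0.065 CPM and 32.8 and 1.44 CPM, and Gpihbp1, Cd93 and Sparcl1 were at 22.6 and 0.04 CPM, 44.7 and 1.88 CPM and 22.5 and 0.355 CPM. The share of endothelial-like cells moved with them, from 15.8% to 0.278%. Smooth muscle contractile and myofibroblast genes were higher in 2 and lower in 2 of 15 (median −0.24), and pericyte or smooth muscle markers in 3 and 2 of 11 (median −0.55). Mmp3, stromelysin, was at 25.7 and 0.516 CPM. Interferon response genes were lower in 11 of 15 (median −2.04), with Isg15 at 58.7 and 4.30 CPM and Bst2 at 186 and 20.2 CPM. Macrophage markers were lower in 4 of 11 (median −0.80). In all, 282 genes were higher and 213 lower, and thinning every cell to 1000 UMIs gave 357 and 392.

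Between Days 7 and 10, most fibrillar collagen and matrix genes were higher on Day 10. Sfrp1, a secreted Wnt antagonist (chromosome 8, 23411502 to 23449632), was at 8.59 and 137 CPM (log2 ratio 3.84), Aspn, a small matrix proteoglycan, at 1.58 and 30.5 CPM, Medag at 1.66 and 30.3 CPM, Ccn5 at 7.41 and 91.5 CPM and Capn6 at 2.10 and 24.4 CPM. Of 16 fibrillar collagen and matrix genes 10 were higher and 0 lower (median 1.66, percentile 100). Col3a1 was at 133 and 831 CPM, Col1a1 at 438 and 2333 CPM and Col6a1 at 37.9 and 209 CPM. Progenitor or fibroblast markers were higher in 5 and lower in 0 of 12 (median 0.69). The fibroblast-like class, cluster 17, whose leading genes include Col1a1 and Col3a1, went from 1.32% to 45.9% of cells, and clusters 7, 10, 17 and 20 together from 34.2% to 52.2%. Unfolded protein response genes were higher in 3 of 14 (median 0.76), with Trib3 at 2.13 and 13.2 CPM and the chaperone gene Hspa5 at 641 and 1558 CPM. Cholesterol synthesis genes were higher in 3 of 15 (median 0.71), with Cyp51 at 45.4 and 137 CPM and Hmgcs1 at 36.6 and 109.8 CPM, with none of either list lower. Of 11 basement membrane genes 4 were higher (median 0.89), with Col15a1 at 24.8 and 141 CPM, and of 12 matrix proteases and inhibitors 6 (median 0.81), with Mmp14 at 97.9 and 253 CPM. Endothelial markers moved with them, 4 of 12 being higher and 0 lower (median 0.77, percentile 100), and endothelial-like cells went from 0.278% to 1.14%. Sct was at 514 and 23.1 CPM (−4.42), Dynap at 50.5 and 1.96 CPM, the water channel gene Aqp5 at 50.4 and 3.51 CPM, Lce1g at 40.2 and 5.56 CPM and Car3 at 28.4 and 3.81 CPM. In all, 216 genes were higher and 40 lower; TMM factors gave 148 and 58 and median-of-ratios factors 133 and 68. The median log2 ratio of all genes was 0.16, −0.08 and 0.11 over the steps to Days 3, 7 and 10 in CPM, and −0.03, 0.00 and 0.01 with TMM factors.

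Heart genes were examined singly because the series names a cardiac transition. Of the 16 cardiomyocyte markers, Tnnt2 was at 1.13, 3.23, 34.6, 666 and 894 CPM over the 5 days, Actc1 at 0, 0.046, 6.33, 416 and 607 CPM and Myh7, the slow and beta-cardiac myosin heavy chain, at 0, 0.009, 0.063, 5.56 and 24.7 CPM. Tnnc1, Ttn and Actn2 were at 1124 and 970.5 CPM, 841 and 1692 CPM and 102 and 106 CPM on Days 7 and 10. The other 10 markers had under 2 CPM on average. Myh6, the alpha-cardiac myosin heavy chain (chromosome 14, 54941921 to 54966927), was at 0.081 and 0.144 CPM on Days 7 and 10, Tnni3, cardiac troponin I, at 0.597 and 0.315 CPM. The atrial light chain gene Myl7 was at 0 and 0.014 CPM, the ventricular light chain gene Myl2 at 0.25 and 2.31 CPM. Mybpc3 was at 0.008 and 0 CPM, Ryr2 at 0.024 and 0.116 CPM, Pln at 0.008 and 0.075 CPM and the natriuretic peptide genes Nppa and Nppb at 0.169 and 0.116 CPM and 0.823 and 0.575 CPM. Of the 16 cardiac transcription factors 4 were measured, with a median log2 ratio on Day 10 of 0.01 (percentile 18.96). Mef2c (chromosome 13, 83504034 to 83667080), which skeletal muscle also uses, was at 27.0, 18.97, 20.4, 194 and 278 CPM and Gata6 at 26.4, 12.2, 17.9, 8.90 and 13.6 CPM. Nkx2-5 (chromosome 17, 26838664 to 26845009) was at 0, 0.009, 0.073, 0.105 and 0.089 CPM, Gata4 (chromosome 14, 63198922 to 63271692) at 0, 0, 0.042, 0.29 and 0.089 CPM, and Tbx5, Hand2, Isl1 and Myocd at 1.05, 0.931, 1.46 and 0.753 CPM on Day 10. Gata5, Hand1 and Irx4 had no UMI in any library.

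After thinning, 0.122%, 0.326%, 3.29%, 29.1% (28.0 to 30.2) and 28.4% (27.5 to 29.4) of cells had a Tnnt2 UMI on Days 0, 1, 3, 7 and 10, and 19.4% and 22.7% of Day 7 and Day 10 cells had an Actc1 UMI. In clusters 18 and 19 of Day 10, 95.8% of 1731 thinned cells had a Tnnt2 UMI and 83.5% an Actc1 UMI. In cells of that day assumed to lack both genes, the thinned shares were 6.93% and 6.93% of 101 endothelial-like cells. In 4617 cells of clusters 7, 10, 17 and 20, of which only 17 was named, they were 4.18% and 6.09%. Thinned shares of that size were read as background, which rests on this assumption. Low expression in these cells was not told apart from free RNA. Before thinning, the median depths of these 3 sets were 11374, 8460 and 19796 UMIs. Unthinned, 71.8% of Day 10 cells had a Tnnt2 UMI and 70.1% an Actc1 UMI. The unthinned shares were 99.7% and 97.9% in clusters 18 and 19 and 47.5% and 54.5% in endothelial-like cells. In clusters 7, 10, 17 and 20 they were 60.6% and 68.7%. Unthinned shares of that size were read as background on the same assumption. The same clusters 18 and 19 held Tnnt2 at 3179 and 5336 CPM on Days 7 and 10, against Tnni3 at 0.535 and 0.406 CPM and Myh6 at 0.401 and 0.856 CPM. Myh6 and Nkx2-5 each had a UMI in 0.0113% of thinned Day 10 cells, and Myl7 in none, which allows a UMI in up to 0.0339% of cells at that depth and sets no limit on cells expressing it. Unthinned, 0.226% had a UMI of Myh6, 0.124% of Nkx2-5 and 0.0226% of Myl7.

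**Figure D4:**
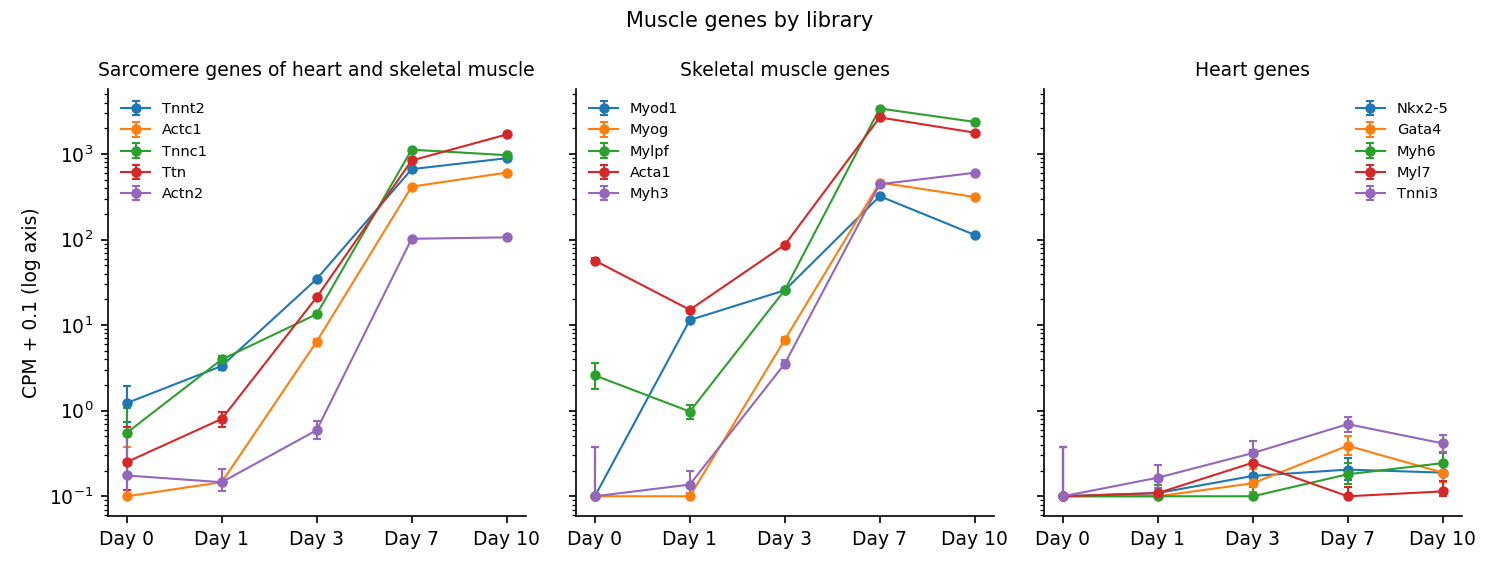
CPM + 0.1 on a log axis (vertical) by library (horizontal) for sarcomere genes shared by heart and skeletal muscle, skeletal muscle genes and heart genes, with exact Poisson 95% intervals as error bars; genes were picked after their values were seen. Tnnt2 is at 666 and 894 CPM and Mylpf at 3406 and 2376 CPM on Days 7 and 10, while Nkx2-5, Gata4, Myh6, Myl7 and Tnni3 stay under 1 CPM in every library.

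Genes of the LIF receptor and STAT3 response were mostly lower after Day 0. Of 19 members 10, 12, 11 and 11 were lower and 3, 3, 2 and 3 higher on Days 1, 3, 7 and 10, with medians of −1.02, −1.55, −1.10 and −1.35 (percentiles 0.05, 0.00, 0.03 and 0.00). Timp1 went the other way, as given above. Socs3, the feedback inhibitor that STAT3 induces (chromosome 11, 117966079 to 117970047), was at 234, 18.6, 8.56, 28.7 and 27.1 CPM, the acute phase gene Serpina3n at 81.4, 2.70, 1.58, 0.331 and 1.96 CPM, Junb at 1754, 302, 162, 175 and 143 CPM and Ccl2 at 322, 2232, 653, 164 and 91.1 CPM. Lifr, the receptor of LIF (chromosome 15, 7090614 to 7197489), was at 43.1, 7.74, 7.57, 8.80 and 15.1 CPM, Stat3 at 177, 60.8, 62.3, 83.6 and 109 CPM and Lif itself at 0.829, 29.9, 22.98, 3.53 and 3.54 CPM; these 3 were chosen after their values were seen. The immediate early list, which shares Junb with this one, was lower in 14, 15 and 15 of 16 members on Days 3, 7 and 10 (medians −3.69, −3.71 and −3.94).

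Transcripts of dividing cells were rare on Day 0. After thinning, 0.122%, 1.79%, 32.6% (31.3 to 34.0), 37.6% (36.5 to 38.7) and 25.3% (24.4 to 26.2) of cells had at least 2 UMIs of the G2/M list on Days 0, 1, 3, 7 and 10, and 0.538%, 14.3%, 25.1%, 27.0% and 16.8% of the S phase list. Unthinned, the G2/M shares were 0.514%, 15.6%, 76.9%, 84.1% and 65.2% and the S shares 6.21%, 83.0%, 88.2%, 90.7% and 81.9%. All 20 S phase genes were at least 2-fold higher on Day 3 than on Day 0, and 17, 18 and 16 on Days 1, 7 and 10 (medians 2.82, 3.17, 3.14 and 3.08), with Rrm2, a subunit of ribonucleotide reductase, at 0.753, 34.3, 216, 226 and 121 CPM. For G2/M genes, 17 were higher on Day 1 and all 20 on Days 7 and 10 (medians 1.94, 5.33 and 5.09). Among cell cycle inhibitors and p53 targets 7 of 13 were higher and 4 lower on Day 10 (median 1.31), with Cdkn2a at 0.075 and 106 CPM and Cdkn2c at 464 and 20.2 CPM. Within cluster 19, the thinned G2/M and S shares were 2.06% and 3.09% of 1068 cells of Day 7 and 0.781% and 1.80% of 1280 cells of Day 10. Within cluster 8, they were 0% and 4.98% of 1206 cells of Day 1 and 1.64% (0.849 to 2.84) and 6.003% of 733 cells of Day 3. Free RNA alone gave no more than these shares in those cells.

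The remaining lists are given for Day 10 against Day 0, with members higher, members lower and the median log2 ratio. Glycolysis genes were higher in 11 and lower in 1 of 14 (median 2.22; the lactate transporter gene Slc16a3 at 0.075 and 94.8 CPM), and nuclear genes of oxidative phosphorylation lower in 6 of 17 (median −0.74; Sdha at 272 and 87.5 CPM). Mitochondrially encoded genes, on which the cell filter acted, were lower in 12 of 13 (median −1.46). Actin cytoskeleton genes were higher in 12 of 15 (median 2.15; Actn1 at 21.5 and 432 CPM), and 13 of 15 smooth muscle contractile and myofibroblast genes were higher (median 5.70). Pericyte or smooth muscle markers were higher in 5 and lower in 4 of 11 (median −0.76). The bone and cartilage list was higher in all 5 measured members (median 2.92; Spp1, osteopontin, at 4.82 and 1804 CPM and Runx2 at 1.81 and 34.6 CPM). Its other members fell under the cutoff of 2 CPM on average, which includes Day 10 and so partly sets this count. Wnt genes were higher in 7 and lower in 2 of 12 (median 1.57). Notch genes were higher and lower in 5 and 2 of 10 (median 0.40). TGF-beta and BMP genes were higher and lower in 9 and 2 of 15 (median 1.61), and angiogenic factors in 6 and 4 of 13 (median 0.58). Lysosome genes were higher and lower in 2 and 2 of 14 (median 0.30). For the lists of fat progenitor states, interstitial DPP4 progenitor genes were higher in 2 and lower in 4 of 8 (median −0.79; Pi16 at 14.5 and 0.246 CPM). Committed ICAM1 preadipocyte genes were higher and lower in 2 and 8 of 11 (median −2.76; Fabp4 at 45401 and 147 CPM) and CD142 regulatory progenitor genes in 2 and 1 of 4 (median 0.56; Mgp at 21.8 and 289 CPM). The ICAM1 list shares Pparg, Fabp4, Lpl and Cd36 with the adipocyte markers, so it does not separate a preadipocyte state from fat cells. Markers of dendritic cells were lower in 4 of 4 (median −3.84; Cd74 at 38.3 and 0.144 CPM) and of Schwann cells in 3 of 4 (median −2.49). The T or NK, epithelial and pluripotency lists had 0 members at 2 CPM on average, the mesothelial list 1 (Krt19 at 0.527 and 36.1 CPM) and the B list 2 (Ighm at 74.7 and 0.055 CPM and Igkc at 11.3 and 0 CPM).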

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

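All tests in this part were chosen after the result was seen. The Day 0 barcodes left out for a mitochondrial share of at least 20% held fat cell transcripts, a signal in data outside the comparisons. In these 7004 barcodes, with a median of 2935.5 UMIs and 30.4% mitochondrial UMIs, Adipoq was at 2533 CPM (2514 to 2552), against 3184 CPM in the kept cells. Cfd was at 28016 CPM against 35056 CPM, and Car3 at 14656 CPM against 17819 CPM. Pdgfra, a receptor of fat progenitors, had 2 UMIs there (0.07 CPM) and 5.50 CPM in the kept cells.

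The pattern was that Day 0 barcodes, described in the labels as progenitors, held transcripts of fat cells. Free RNA of a single composition was argued against, since the 12 adipocyte markers varied between barcodes of clusters 0 and 2 with a mean chi-square of 2.22 per degree of freedom (2.15 to 2.29), where 1.01 was simulated for a fixed composition. Nuclear RNAs were higher in cluster 2 than in cluster 0 (median log2 ratio 2.96; Malat1 at 72628 and 9345 CPM), so a candidate explanation for the difference between these clusters is barcodes with and without a nucleus. Progenitors carrying fat cell RNA stay open. The 12 progenitor markers in these barcodes reached 15.9% of their level in Day 1 cluster 7, which decides nothing. They reached 1.75% of their level in 72 progenitor-like cells of Day 0. Such markers had named these cells, so this comparison is partly set by the naming. In the 72 cells Pdgfra was at 210 CPM, Dcn at 6215 CPM, Col3a1 at 6276 CPM and Ly6a at 964 CPM. Col3a1 weighed most in the 15.9%, at 208 CPM in 3714 of these barcodes and 56.9 CPM in Day 1 cluster 7. Pdgfra (0.087 and 103 CPM), Dcn (7.84 and 480 CPM) and Col1a2 (23.4 and 264 CPM) were lower in these barcodes. So were Cd34 (1.05 and 15.7 CPM) and Ly6a (32.7 and 120 CPM). How this RNA entered the library also stays open, and no biological explanation was tested.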

How the results depend on the processing

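The alternatives that took Day 1 as the reference, or left out mitochondrially encoded genes, genes on X and Y, the top 5% of Scrublet scores, or erythroid-like, B-like and mast-like cells, were chosen after the results were seen. No paired analysis was possible because each day had 1 library. Of 202 recomputed counts of genes 36 moved by over 1.5 times, and of 3864 list medians 183 moved and 5 changed sign. Of 176 class shares 48 moved beyond their counting interval, of 50 cycling shares 24 and of 800 shares of cells with a UMI of a heart gene 242. No count moved by that much without a cell filter, under 10% mitochondrial UMIs, with doublets kept, with a pseudocount of 5 CPM, or under the added alternatives other than the Day 1 reference. The comparison restricted to progenitor or fibroblast-like cells was not run, since cluster 17, the sole such cluster, held 0 cells on Days 0 and 3, 1 on Day 1 and 95 on Day 7. The alternative for normalized values did not apply to counts. Depth limits Day 0 most, where 3 UMIs amount to 0.226 CPM against 0.0205 CPM on Day 10.

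A floor of 5 CPM gave 2426, 2192, 2232 and 1926 lower genes on Days 1, 3, 7 and 10 against Day 0. Between sampled days it gave 936 higher and 305 lower to Day 3, 561 and 423 to Day 7, and 386 and 89 to Day 10. A floor of 50 CPM gave 1274 higher and 895 lower on Day 1, 1498 and 854 on Day 3, 1343 and 845 on Day 7 and 1464 and 787 on Day 10 against Day 0, and 245 and 76, 131 and 113, and 119 and 17 over the steps to Days 3, 7 and 10. The floor sets how many genes can be counted. From Day 1 to Day 3, TMM factors gave 263 lower and median-of-ratios factors 266. From Day 7 to Day 10 the latter gave 133 higher and 68 lower. From Day 3 to Day 7, weighting every cell alike gave 384 lower and thinning 392. With Day 1 as the reference, Days 3, 7 and 10 had 499, 779 and 1178 higher and 149, 437 and 512 lower genes. The cause of these moves was not tested.

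List medians of Day 1 over Day 0 changed sign under 10% mitochondrial UMIs for progenitor or fibroblast markers (−0.59), fibrillar collagens and matrix (−0.47) and angiogenic factors (−0.035), as did that of macrophage markers for Day 3 over Day 0 (−0.072). Without a cell filter the erythroid median of Day 1 over Day 0 was 0.41. The cause was not tested.

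With at least 4 UMIs required, the G2/M shares were 0, 0.422, 12.7, 19.5 and 14.01% on the 5 days. At the cells' own depth they were 0.514, 15.6, 76.9, 84.1 and 65.2%, since more UMIs were counted per cell, and without a cell filter 0.027% on Day 0. On Day 10, at least 2 UMIs were found in 19.9% of cells for Tnnt2, 13.8% for Actc1 and 0 for Myh6 and Nkx2-5. At their own depth, 71.8, 70.1, 0.226 and 0.124% had a UMI of Tnnt2, Actc1, Myh6 and Nkx2-5, and without a cell filter 29.8% had one of Tnnt2 and 0 one of Nkx2-5.

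At a Leiden resolution of 1.0, cardiomyocyte-like cells held 1.33% of Day 7 and 13.96% of Day 10 and skeletal muscle-like cells 22.2% and 5.63%. The cardiomyocyte-like cluster was led by sarcomere genes that heart and skeletal muscle share and by skeletal muscle markers, and 1330 of its 1331 cells came from skeletal muscle-like cluster 19, so these shares moved through the names. At this resolution, fibroblast-like cells held 1.35% of Day 0, 0.347% of Day 7 and 14.1% of Day 10, adipocyte-like cells 2.41% of Day 3, macrophage-like cells 3.55% and T or NK-like cells 1.57% of Day 1, and endothelial-like cells 1.85% of Day 3, where 648 cells of cluster 8 fell in an unnamed cluster, and 0.014% of Day 7. With doublets kept, fibroblast-like cells held 42.03% and skeletal muscle-like cells 20.9% of Day 10, and Schwann-like cells 0% of Day 0. Without a cell filter, fibroblast-like cells held 28.9% of Day 10, adipocyte-like cells 95.8% of Day 0, endothelial-like cells 3.48% of Day 0, 18.5% of Day 1 and 14.2% of Day 3, and skeletal muscle-like cells 19.9% of Day 7 and 20.8% of Day 10. Erythroid-like cells then held 0.216% of Day 0 and 3.25% of Day 1, Schwann-like cells 0.126% and B-like cells 0% of Day 0. With each library clustered on its own, 0% of Day 10 was fibroblast-like, 0% of Day 0 adipocyte-like, 3.40% of Day 1 macrophage-like and 1.57% T or NK-like, and 6.20% of Day 3 skeletal muscle-like and 3.32% adipocyte-like. Macrophage-like and B-like cells then held 0% and dendritic-like cells 0.709% of Day 0, macrophage-like cells 0.667% and fibroblast-like cells 0% of Day 7, and pericyte or smooth muscle-like cells 0.396% of Day 10. With each library on its own, leading genes were ranked within it, which works against a class that fills it, such as adipocyte-like cells on Day 0. The cause of the other moves was not tested.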

Other observations

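All tests and genes in this part were chosen after the results were seen. Counts within clusters took genes with at least 50 CPM on the higher day. Within endothelial-like cluster 8, 266 genes were at least 2-fold higher and 129 lower on Day 3 (733 cells) than on Day 1 (1206 cells). Xist had the largest ratio upward, at 0.11 CPM on Day 1 and 609 CPM on Day 3. Ddx3y had the largest downward, at 78.5 and 0 CPM. The sex-linked difference of the Day 1 library thus goes with this comparison too, and its part in the other genes was not separated from that of time. At a resolution of 1.0 the days fell apart, with 1150 of these Day 1 cells in an endothelial-like cluster and 648 of these Day 3 cells in an unnamed one. In this cluster Ankrd1 was at 40.3 CPM on Day 1 and 1514 CPM on Day 3, against 375 CPM in the whole Day 3 library. Fn1 was at 40.3 and 801 CPM, against 364 CPM, and Vwf, the clotting factor carrier of endothelium, at 22.0 and 204 CPM. Gdf15, a stress-induced cytokine, was at 649 CPM on Day 1 and 58.0 CPM on Day 3. The fat cell transcript Cfd was at 798 and 49.6 CPM, and free RNA was not separated from these counts.

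Within skeletal muscle-like clusters 18 and 19, 135 genes were at least 2-fold higher and 57 lower on Day 10 (1731 cells) than on Day 7 (1684 cells). At a resolution of 1.0, 963 cells of cluster 19 from Day 7 and 44 from Day 10 fell in a skeletal muscle-like cluster, and 96 and 1234 in the cardiomyocyte-like one. Myh8, the perinatal myosin heavy chain, was at 147 CPM on Day 7 and 898 CPM on Day 10, Myh7 at 28.6 and 156 CPM, and Cdkn1c, a cell cycle inhibitor, at 118 and 829 CPM. Sct was at 2214 and 142 CPM. Pax7, the transcription factor of muscle stem cells (chromosome 4, 139737062 to 139833528), was at 0.075, 0.406, 2.32, 14.9 and 17.7 CPM over the 5 libraries and Myf5 at 0.226, 0.351, 0.808, 7.32 and 9.75 CPM.

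The sarcomere genes of Days 7 and 10 were weighed between heart and skeletal muscle. In clusters 18 and 19 the heart-restricted genes Myh6, Myl7, Tnni3, Mybpc3, Nppa, Ryr2 and Pln together reached 0.0101% of the level of Tnnt2, Actc1 and Tnnc1, which argues against a heart muscle programme there. Free RNA of a single composition is argued against as the only source, since the UMIs of Tnnt2, Actc1 and Tnnc1 varied between Day 10 cells with a mean chi-square of 3.805 per degree of freedom (3.65 to 3.95), where 1.005 was simulated for a fixed composition. The skeletal markers Myod1, Myog, Acta1, Mylpf, Tnnt3 and Tnni2 reached 2.73 times the level of those 3 genes, but 4 of the 6 were among the leading genes of these clusters, so this decides nothing. Of the explanations weighed here, a skeletal muscle programme is the one that no value argued against. It had no separate test, and where such cells came from was not tested.

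The Y-linked transcripts of the Day 1 library were weighed too. Loss of Xist in culture is argued against by 10757 UMIs of Y-linked genes on Day 1. A single cell type is argued against, since the lowest Y-linked level of any Day 1 cluster with at least 20 cells was 60.3 CPM. Cells from animals of the other sex may account for it, with Y-linked genes at 99.3 CPM on Day 1. Whether the library was mislabelled or animals differed between days was not tested.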
